A study of Drosophila melanogaster with 12 samples.

How the data were processed

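The series covers RNA sequencing of Drosophila melanogaster testis in 12 libraries. The libraries fall into 5 groups. SC is meiotic germ cells and SG is mitotic germ cells, both laser dissected from wild-type testes, with 3 libraries each. SG-tut, SG-bam and SG-bgcn are whole testes mutant for tut, bam or bgcn, with 2 libraries each. Per the labels' protocols, SG and SC cDNA was made with a low-input full-length cDNA kit and tagmented with Nextera XT, while RNA of the mutant testes was extracted with Trizol, enriched for mRNA with oligo(dT) beads and made into libraries with an Illumina mRNA-Seq kit. Genotype, dissection and kit therefore change together between the mutant testes and SC. The labels do not say whether libraries of a group came from separate flies, so the authors' P may measure only technical spread. The labels do not state the strand setting of the counting.

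Per the submitters' processing notes, the authors used CASAVA, FastQC 0.11.3, Trimmomatic 0.33, TopHat2 2.1.0, Cufflinks 2.2.1, Cuffdiff 2.2.1 and DESeq2 with genome build dm6. The role of each tool, the way 3′ extensions were defined and the test behind P are not given in the sources used here. The 4 deposited tables each compare 1 mitotic group with SC, gene by gene. Each row gives, per the file headers, the position and length of a 3′ extension, the average level of that extension and of the gene in both groups, and the part of the 3′ reads that lie in the long form. Both levels are the authors' averages per group, their unit is not named in the sources used here, and no values per library are used here. The share of the extension is deposited as a fraction from 0 to 1. It equals, in every row, the extension level plus 1e-05 over the gene level plus 1e-05, set to 1 where above 1. Shares are printed below as percentages, and 100% includes genes whose extension level exceeded the gene level. The log2 folds of the mitotic group over SC were computed by the authors, per the file headers, and those of the extension and its share include the added 1e-05. A gene or extension listed at 0 is given without a fold, because an exact 0 can be a failed estimate, and no direction is read from a single such gene, although counts of calls include it on the side the authors list. RpL5, needed by every cell, has a gene level listed at 0 in SG-bgcn. The p-value (P) and FDR of each row are the authors' own.

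The tables hold selected genes. In every listed row P was below 0.05, the extension level differed by more than 2 times, and the share moved the same way as the extension. The number of tests behind each FDR was recovered from the ratio of P to FDR, which under Benjamini-Hochberg adjustment gives a gene's rank. This gave 5813 tests for SG, 5580 for SG-tut, 6142 for SG-bam and 5592 for SG-bgcn, with ranks whole to within 0.01 in 87.6%, 73.0%, 74.1% and 73.9% of rows. On simulated P values the number of tests came out exact in 10 of 10 draws for each table. The tables list 751, 627, 638 and 618 genes. The highest rank listed corresponds to 71.7%, 82.0%, 81.3% and 83.8% of the tests, so most genes with a low P are not listed and their folds are unknown. The gene level of SC was the same in every table for 684 of 684 genes listed in at least 2 of them. Depth per library is unknown.

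The planned tests assumed expression values. As the tables hold comparisons of 3′ extensions with group averages, the planned branch for such tables was used: a gene was called at an authors' FDR of 0.05 or less, with the direction of the authors' log2 fold of the share, and no test of single genes was run. Shares of genes on 1 side carry exact (Clopper-Pearson) 95% intervals. They cover counting error only and treat genes as independent, which they are not. Counts were compared with 2-sided Fisher's exact tests and extension lengths with 2-sided permutation tests of 100000 resamples. Overlaps between pairs of comparisons are given beside the number that independent lists would share, n1 × n2 / N, per direction, with the smaller number of recovered tests as N. Overlaps of more comparisons are given without such a number. Comparisons with SC share the SC averages, and without libraries that effect was not simulated. Extensions were set against the exons and annotated 3′ UTRs of Ensembl release 115 (BDGP6.54, the same assembly as dm6). Of the SG table's identifiers 734 matched and 17 did not, and the locus was identical for 729. The corresponding counts were 620, 7 and 615 for SG-tut, 633, 5 and 627 for SG-bam, and 610, 8 and 605 for SG-bgcn. All coordinates are dm6 and count from 1.

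Before the data were examined, 24 gene lists and the rule for named genes were fixed. The named genes are bam, bgcn, tut and mei-P26 whether called or not, up to 4 called members per list with the largest log2 folds and values above 0 in both groups, the 10 largest positive and 10 largest negative folds among called genes with a group mean of at least 1 in both groups, and the 5 called genes with the highest level in each group. Genes named only by a CG number may be summarised. Folds here are those of the share, and extensions listed at 0 took no part in the ranking. Other genes are marked as chosen after their values were seen. Each list was tested by Fisher's exact test for the direction of its called members against other called genes. P is unknown for members outside the tables, so no count adjusted over the list alone can be given. In simulations of 200 draws per table with lists of 200 genes, far larger than the 1 to 12 called members of the real lists, the list test found a planted difference of 90% against 60% in 100.0% of draws in each table. With lists as large as the largest real one, of 12, 7, 9 and 5 called members, it found that difference in 70.0% (SG), 47.5% (SG-tut), 39.5% (SG-bam) and 0% (SG-bgcn) of draws. These draws set the other genes at 60%, but 91.9% (SG), 74.1% (SG-tut), 76.9% (SG-bam) and 75.2% (SG-bgcn) of the real calls lay on the mitotic side. The rates therefore do not give the power of the list test on the real calls. With every member on the mitotic side, 0 lists could pass in any comparison. With lists of 200 genes it called 4.0% (SG), 2.5% (SG-tut), 8.0% (SG-bam) and 4.5% (SG-bgcn) of lists with no difference. The computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Alternatives covered the FDR threshold, minimum folds, minimum levels, extensions at 0, another added constant, exons of other genes and extensions inside the annotated locus.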

Results

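Messenger RNAs of 1 gene can end at different 3′ positions, and the stretch between a proximal and a more distal end is called an extension here. The deposited tables compare how much of each gene's signal lay in such an extension between mitotic germ cells and meiotic spermatocytes of the Drosophila testis. Spermatogonia (SG) and spermatocytes (SC) were laser dissected, with 3 libraries each. Testes mutant for tut, bam or bgcn, with 2 libraries each, supplied 3 further mitotic groups, because germ cells that lack these genes keep dividing and do not become spermatocytes. The question of each comparison was which genes change their 3′ ends between mitotic and meiotic germ cells. All values are the authors' group averages, with no replicate error in the tables, and the unit of the levels is not named. Depth per library is unknown. The extension share is the extension level as a percentage of the gene level. Whether the authors' FDR tests the extension level or its share is not stated in the sources used here. An FDR printed beside a share is therefore not read as a test of that share. The share changed at least 2-fold in 664 of 724 calls in SG and 531 of 609 in SG-tut. It did so in 530 of 610 in SG-bam and 502 of 584 in SG-bgcn.

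Most listed genes had a higher extension share in dissected spermatogonia than in spermatocytes. An FDR of 0.05 was passed by 724 genes in the authors' deposited table, and 665 of them (91.9%, 95% exact binomial interval 89.6 to 93.7%) had the higher extension share in SG, against 59 in SC. The extension share of stg, the Cdc25 phosphatase that triggers entry into mitosis, was 1.22% in SC and 15.4% in SG (FDR 3.38e-18 in the authors' deposited table). The gene level of stg in SC was low, as given below, so its SC share rests on little signal. For mei-P26, a TRIM-NHL protein that restrains germ cell proliferation, the authors' deposited table gives 0.942% in SC and 100% in SG (FDR 2.6e-31). In the other direction the extension share of cwo, a transcriptional repressor of the circadian clock, was 57.8% in SC and 1.11% in SG (FDR 0.00686 in the authors' deposited table). The gene level of cwo was 1.78 in SC and 8.46 in SG in the authors' deposited table. Its SC share therefore also rests on little signal, here and in the mutant comparisons. The median share of the 665 genes was 0.809% in SC and 14.0% in SG, and that of the 59 genes was 4.05% in SC and 0.626% in SG.

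**Figure D1:**
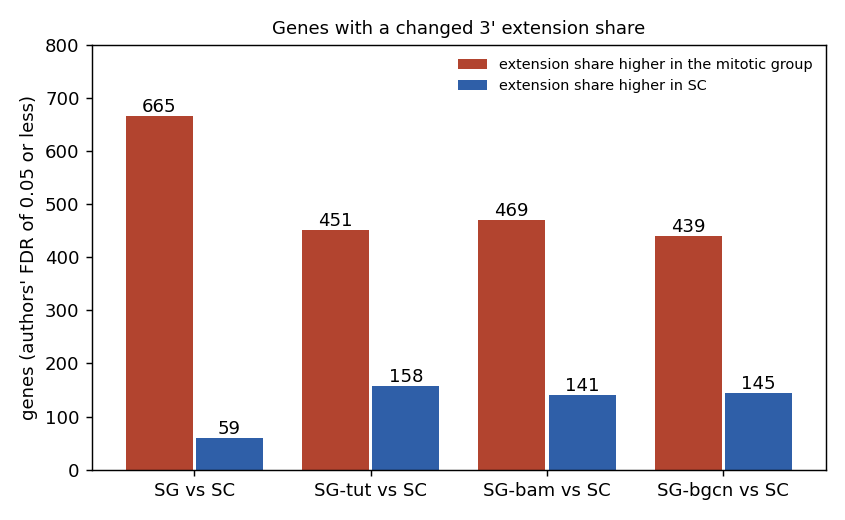
Number of genes past an authors' FDR of 0.05 in each comparison with SC (horizontal axis), split by the group with the higher extension share. Bars start at 0, and the split was 665 to 59 for SG, 451 to 158 for SG-tut, 469 to 141 for SG-bam and 439 to 145 for SG-bgcn.

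Among the germline regulators fixed for study, bam and bgcn were not listed in any of the 4 tables, so the mutant groups could not be checked at those genes. tut, which encodes an RNA-binding partner of Bam and Bgcn, was listed for SG only, with a share of 0.173% in SC and 0.856% in SG in the authors' deposited table (FDR 0.00158). The SG extension of mei-P26 spans chromosome X from 9172930 to 9175379 and lies wholly within the annotated 3′ UTR. That of stg spans chromosome 3R from 29251523 to 29252142 on the minus strand, with 317 of its 620 bases in the annotated 3′ UTR and the rest past the annotated end of the gene at 29251826. The gene level of stg itself was 0.57 in SC and 23.53 in SG in the authors' deposited table. At that SC level the SC share of stg rests on little signal, here and in the mutant comparisons.

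**Figure D2:**
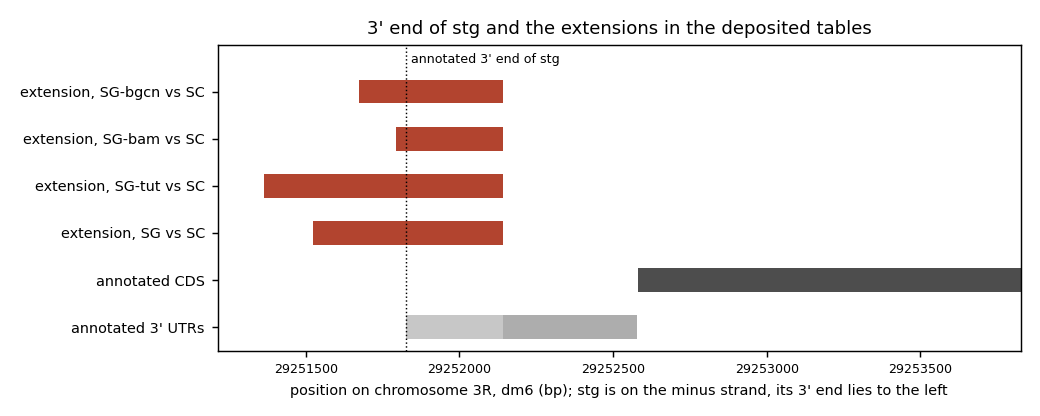
Map of the 3′ end of stg on chromosome 3R (position in bp, dm6), with annotated 3′ UTRs in grey, coding sequence in dark grey and the extension of each deposited table in red. The extensions begin at the same base next to the proximal 3′ UTR and reach past the annotated end at 29251826 by different lengths.

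Of the 24 gene lists, 16 had a called member in SG, and every called member had the higher share in SG. As 91.9% of all calls went that way, 0 of the 16 lists could pass the test of direction with every member on the SG side, so it cannot show whether a list leaned further to SG than the other calls (0 lists at an adjusted or unadjusted p below 0.05 by Fisher's exact test, smallest p = 0.613, adjusted p = 1). The cleavage and polyadenylation machinery had 3 called members. The share of su(f), a cleavage stimulation factor subunit, was 1.94% in SC and 30.9% in SG (FDR 1.91e-14), that of Cdk12, a kinase of RNA polymerase II, 0.186% and 5.88%, and that of Fip1 0.489% and 1.53% in the authors' deposited table. The splicing and RNA-binding regulators had 4 called members. Among them the authors' deposited table gives 6.53% in SC and 100% in SG for mub (FDR 6.14e-114), 1.54% and 25.4% for Sxl, 0.357% and 5.14% for mbl, and 0.285% and 1.89% for Hrb27C.

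Cytosolic ribosomal proteins were the list with most calls, 12 of 12 with the higher share in SG, at very small shares. The authors' deposited table gives RpL37a 0.00253% in SC and 0.036% in SG, RpS7 0.00207% and 0.0284%, RpL10 0.00338% and 0.039%, and RpS26 0.0134% and 0.084%. Their gene levels were much higher in SG, with 802.7 in SC and 9303.17 in SG for RpS7 in the authors' deposited table. Spindle and cyclin genes had 2 called members, stg and the checkpoint kinase BubR1, whose share was 0.15% in SC and 7.58% in SG in the authors' deposited table. The lists for stem cell and spermatogonial regulators, spermatid differentiation, the general proteasome core and ribosome biogenesis had 2 called members each. The authors' deposited table gives shares of 0.0442% in SC and 6.36% in SG for r-cup, 0.0976% and 100% for the spermatid mitofusin fzo, and 0.015% and 0.158% for Prosalpha4. The nucleolar helicase gene pit had 0.97% and 2.25% and Nnp-1 0.0377% and 0.681% in the authors' deposited table. Prosalpha3 had 0.514% and 1.45% in the authors' deposited table, and its extension touches an exon of CG10543. Single called members in SG were aly of the spermatocyte transcription programme, the cohesin subunit vtd, robls54B of the axoneme list, the replication factor gene Gnf1 and AGO3 of the piRNA pathway. Their shares were 0.152% in SC and 15.5% in SG for aly, 0.0949% and 3.81% for vtd, 0.765% and 48.9% for robls54B, 0.0296% and 5.26% for Gnf1 and 4.27% and 39.5% for AGO3 in the authors' deposited table. The SG extension of fzo touches an exon of cnc and that of robls54B an exon of mthl3. No member was called in the lists for meiotic cell cycle control, Y-linked fertility genes, testis proteasome and mitochondrial paralogs, accessory gland, mitochondrially encoded, histone or heat shock genes.

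Markers of other testis cells were among the calls. The hub and cyst cell list had 3 called members, with shares of 16.1% in SC and 100% in SG for zfh1, 6% and 100% for CadN and 0.132% and 61.7% for dally in the authors' deposited table. Muscle Tm1 had shares of 4.28% and 6.35% and the collagen gene Cg25C 6.05% and 11.1% in the authors' deposited table. Gene levels of these markers also differed, with 18.18 in SC and 97.18 in SG for Tm1, 0.56 and 7.94 for Cg25C and 2.7 and 11.26 for zfh1, but 138.77 and 5.13 for dally in the authors' deposited table.

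The 10 largest positive log2 folds of the share lay between 9.42 and 11.18, and in all 10 the gene level was lower in SG. They include Pde9 (0.0255% in SC, 38% in SG), Acsl (0.0097%, 11.2%), DIP-theta (0.0996%, 100%), IA-2 (0.00155%, 2.41%), RhoGEF3 (0.1%, 83.5%), Sur-8 (0.0726%, 50.4%) and fzo in the authors' deposited table, with 3 genes named by CG number. The 10 largest negative folds lay between -7.22 and -4.35, and in 9 of them the gene level was higher in SG. They include cwo, RhoGDI (4.05% in SC, 0.117% in SG), metl (11.1%, 0.159%), Surf6 (4.57%, 0.197%) and Dak1 (1.7%, 0.0746%) in the authors' deposited table, with 5 genes named by CG number. The gene level is the divisor of the share. A ranking by the fold of the share thus favours genes whose level moved the opposite way, here and in the mutants below. Among the most abundant called genes, Cyt-c-d, a testis cytochrome c, had a gene level of 2122.16 in SC and 113.48 in SG and a share of 0.0181% and 7.69% in the authors' deposited table. The gene level of smt3, which encodes SUMO, was 2195.43 in SC and 6814.95 in SG, with shares of 0.00119% and 0.0095%, in the authors' deposited table. For RpS25 the shares were 0.0152% and 0.0208% in the authors' deposited table.

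The extensions differed between the directions. In SG, extensions with the higher share had a median length of 606 bases and those with the higher share in SC 350 bases (permutation p = 2e-05, the smallest the resamples can give). An annotated 3′ UTR of the same gene was touched by 386 of 665 (58.0%) and by 4 of 59 (6.78%) of these extensions (Fisher's exact p = 2.29e-15). Exons of another gene were touched by 12.3% and 25.4% (Fisher's exact p = 0.00855, not adjusted). This difference was not seen in the mutants. There the percentages were 17.3% and 14.6% in SG-tut (Fisher's exact p = 0.458) and 17.1% and 14.2% in SG-bam (p = 0.517). In SG-bgcn they were 16.9% and 16.6%. The gene level was higher in SG for 410 of the 665 genes and lower for 255. The table lists 751 of 5813 recovered tests, so the split holds for the listed genes alone.

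X-linked genes were unevenly divided. Of the SG calls on the X chromosome and on chromosomes 2 and 3, 160 X-linked and 486 autosomal genes had the higher share in SG, while 0 X-linked and 59 autosomal genes had the higher share in SC (Fisher's exact p = 2.69e-07, adjusted p over the 4 comparisons 1.08e-06). For 0 of 59 the upper bound of the 95% exact binomial interval is 6.06%. X-linked genes with the higher share in SG include mei-P26, su(f), Sxl, RpL37a, Prosalpha4, Pde9 and r-cup. Chromosome 4 had 19 such genes and 0 in the other direction, and the Y chromosome had 0 calls. The same test gave 82 and 10 X-linked genes in SG-tut (p = 0.000102), 91 and 13 in SG-bam (p = 0.00324) and 79 and 8 in SG-bgcn (p = 8.24e-05), each by Fisher's exact test.

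**Figure D3:**
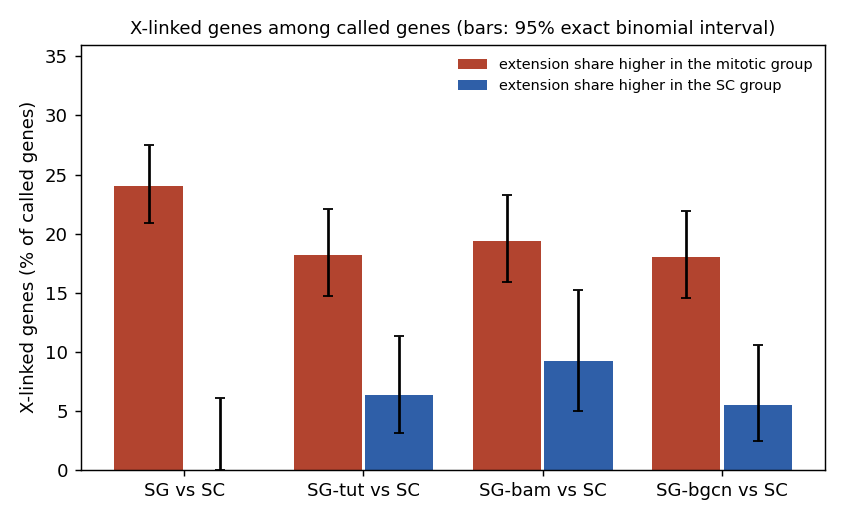
Percentage of X-linked genes among called genes for each comparison with SC (horizontal axis), by the group with the higher extension share. Error bars are 95% exact binomial intervals, and X-linked genes made up 24.1% of calls with the higher share in SG and 0% of those with the higher share in SC.

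In tut mutant testes stg, su(f), mub and the ribosomal protein genes RpL37a and RpL10 had a higher extension share than in SC, as they had in SG, while cwo and jagn had the lower share. For SG-tut, 609 genes passed an FDR of 0.05 in the authors' deposited table, with 451 (74.1%, interval 70.4 to 77.5%) higher in SG-tut and 158 higher in SC. The authors' deposited table gives stg shares of 0.968% in SC and 12.8% in SG-tut (FDR 1.22e-10), su(f) 1.13% and 9%, and mub 6.6% and 29.7%. The spermatid genes dj and ProtB, with gene levels of 4725.77 and 3108.25 in SC against 0.4 and 1 in SG-tut, had extensions listed at 0 in SG-tut in the authors' deposited table, so no direction is read from them. Neither tut nor mei-P26 was listed in this table.

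By list, 12 of the 24 had a called member in SG-tut, and none passed the test of direction against the other calls (0 lists at an adjusted or unadjusted p below 0.05 by Fisher's exact test, smallest p = 0.067, adjusted p = 0.804). Only 3 of the 12 had enough called members to reach that p at any split, so a difference is not excluded. With every member on the mitotic side 0 of the 12 could reach it (smallest possible p = 0.199 by Fisher's exact test). Of 3 called members of the polyadenylation machinery, su(f) and Pcf11 were higher in SG-tut and Clp, a homologue of a cleavage and polyadenylation factor subunit, was higher in SC. The authors' deposited table gives Pcf11 0.519% in SC and 26.2% in SG-tut, and Clp 3.73% and 0.282%. Of 3 spindle genes, stg and Klp3A (0.3% and 25.7%) were higher in SG-tut and Bub1 (1.6% and 0.107%) was higher in SC in the authors' deposited table. Cytosolic ribosomal proteins had 7 of 7 called members higher in SG-tut, among them RpL37a with 0.00224% and 0.0436%, RpL10 with 0.00376% and 0.0588%, RpL13 with 0.0044% and 0.0354% and RpS15Aa with 0.00478% and 0.0301% in the authors' deposited table. For the 2 piRNA pathway members the authors' deposited table gives Hen1 1.82% and 12.9% and AGO3 4.31% and 9.35%. The translational repressor gene pum had 10.2% and 27%, Hrb87F 0.0379% and 0.916%, vtd 0.56% and 1.11% and Prosalpha3 0.181% and 1.46% in the authors' deposited table. The testis proteasome paralog Rpn12R went from 100% to 82.2% at gene levels of 1.73 and 0.16 in the authors' deposited table. The spermatid differentiation list had 2 called members, soti and dj, and the extensions of both were listed at 0 in SG-tut in the authors' deposited table. The remaining called members belonged to the muscle list, with Tm1 at 2.3% and 10.5%, and the accessory gland list, with Acp95EF at 0.166% and 0.42%, in the authors' deposited table. The gene level of Tm1 was 18.18 in SC and 166.96 in SG-tut, and that of Acp95EF, a product of the male accessory gland, was 349.28 and 3979.91 in the authors' deposited table. The Acp95EF extension touches exons of mask and that of Prosalpha3 touches exons of CG10543.

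The 10 largest positive folds in SG-tut, between 10.78 and 13.53, include lov (0.00347% in SC, 52.9% in SG-tut), Mical (0.00224%, 22.9%), mtd (0.029%, 100%) and sbb (0.056%, 100%) in the authors' deposited table. In all 10 the gene level was lower in SG-tut, as for Mical with 1857.93 in SC and 17.98 in SG-tut in the authors' deposited table. The 10 largest negative folds, between -10.25 and -5.37, include Amy-p (55.6%, 0.0446%), cwo (57.8%, 0.439%), BTBD9 (83.8%, 1.16%) and jagn (4.27%, 0.102%) in the authors' deposited table. Of these 20 genes 6 in each direction carry only a CG number. The highest gene levels in SG-tut among called genes were those of ribosomal protein genes such as RpS21, with 515.1 in SC and 7021.48 in SG-tut, and RpS26, with 281.62 and 4910.76, in the authors' deposited table. Median extension length was 670 bases for the higher share in SG-tut and 387.5 bases for the higher share in SC (permutation p = 2e-05, the smallest possible). Annotated 3′ UTRs were touched in 54.8% and 22.8% (Fisher's exact p = 1.80e-12). In 77 of the 158 genes higher in SC the extension was listed at 0 in SG-tut, and their median gene level in SG-tut over all 158 was 0.655. Tissue and kit differ between these testes and dissected SC.

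In bam mutant testes the stem cell and spermatogonial list had 4 called members, all with the higher extension share in SG-bam. The authors' deposited table gives mei-P26 0.764% in SC and 20.9% in SG-bam (FDR 1.74e-07), pum 9.34% and 31.7%, A2bp1 0.00975% and 61.6%, and how 20.5% and 21.3%. The share of how hardly moved, so its call does not show a changed 3′ end. For SG-bam, 610 genes passed an FDR of 0.05 in the authors' deposited table, with 469 (76.9%, interval 73.3 to 80.2%) higher in SG-bam and 141 higher in SC. stg had 2.16% in SC and 46% in SG-bam in the authors' deposited table (FDR 9.51e-17). Klp3A, a kinesin of the spindle midzone, had 0.326% and 47.8% and Incenp, a chromosomal passenger protein, 0.339% and 17.3% in the authors' deposited table.

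In SG-bam 13 of the 24 lists had a called member, and none passed the test of direction (0 lists at an adjusted or unadjusted p below 0.05 by Fisher's exact test, smallest p = 0.127, adjusted p = 1), which only 4 of the 13 had enough called members to pass at any split. With every member on the mitotic side 0 of the 13 could pass, so the test could not show a further lean to SG-bam. All 3 called polyadenylation genes were higher in SG-bam, with su(f) at 2.41% and 15.9%, Pcf11 at 0.519% and 25.6% and Fip1 at 0.69% and 0.738% in the authors' deposited table. Ribosomal proteins had 9 of 9 called members higher in SG-bam, including RpS3 with 0.00519% and 0.396%, RpS7 with 0.00233% and 0.0623% and RpL10 with 0.00377% and 0.0648% in the authors' deposited table. RpS14a, at 0.672% and 11.7% in the authors' deposited table, is uncertain because its extension touches the near-identical copy RpS14b. Of 2 spermatid genes fzo was higher in SG-bam (0.132% and 100%) and Mst84Dd was higher in SC (0.255% and 0.15%) in the authors' deposited table. In the same direction as fzo were aly (0.849%, 8.11%), mub (6.6%, 31.3%), Hrb87F (0.04%, 0.514%), AGO3 (4.31%, 9.98%), pit (0.772%, 1.24%) and Prosalpha3 (0.123%, 0.715%) in the authors' deposited table. Rpn12R had 100% in SC and 67.8% in SG-bam in the authors' deposited table. Among markers of other cells Tm1 had 2.21% and 11% and Acp95EF 0.166% and 2.51%, with gene levels of 18.18 and 157.86 for Tm1 and 349.28 and 673.08 for Acp95EF in the authors' deposited table.

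The 10 largest positive folds in SG-bam lay between 10.12 and 12.87 and include Ndae1 (0.0123% in SC, 100% in SG-bam), Mical (0.00221%, 20.9%), exu (0.00961%, 53.5%), Ir75d (0.0157%, 41.8%), ppl (0.00577%, 7.51%) and A2bp1 in the authors' deposited table. All 10 had the lower gene level in SG-bam, as for exu, which localises bicoid RNA in oocytes and has a male germline transcript, with 1477.6 in SC and 17.86 in SG-bam in the authors' deposited table. The 10 largest negative folds, between -10.74 and -5.23, include Amy-p (55.6%, 0.0314%), Arp1 (27.2%, 0.0192%), Mst57Dc (81%, 0.281%), cwo (55.7%, 0.44%), jagn (4.24%, 0.0598%) and robo1 (37.7%, 1%) in the authors' deposited table. The remaining 4 in each direction carry only a CG number. Median extension length was 758 and 369 bases (permutation p = 2e-05, the smallest possible), and annotated 3′ UTRs were touched in 56.1% and 19.1% (Fisher's exact p = 3.51e-15). In 52 of the 141 genes higher in SC the extension was listed at 0 in SG-bam. The limits of tissue and kit named for tut mutant testes apply here too.

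In bgcn mutant testes the stem cell and spermatogonial list had 5 called members, all higher in SG-bgcn. They include mei-P26 with 0.776% in SC and 19.4% in SG-bgcn (FDR 0.000318), pum with 10.7% and 33.6%, Stat92E, the transcription factor of JAK-STAT signalling, with 37.9% and 56%, and A2bp1 with 0.0101% and 100% in the authors' deposited table. The share of how hardly moved, at 20.6% and 21.6% in the authors' deposited table, so its call does not show a changed 3′ end. For SG-bgcn, 584 genes passed an FDR of 0.05 in the authors' deposited table, with 439 (75.2%, interval 71.5 to 78.6%) higher in SG-bgcn and 145 higher in SC. stg had 1.61% in SC and 24.9% in SG-bgcn in the authors' deposited table (FDR 5.01e-12). The translational repressor gene aret went the other way, from 78.8% in SC to 6.98% in SG-bgcn (FDR 2.2e-48 in the authors' deposited table).

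In SG-bgcn 13 of the 24 lists had a called member, and none passed the test of direction (0 lists at an adjusted or unadjusted p below 0.05 by Fisher's exact test, smallest p = 0.0613, adjusted p = 0.797, for the testis proteasome paralogs), which only 3 of the 13 had enough called members to pass at any split. With every member on the mitotic side 0 of the 13 could pass (smallest possible p = 0.339 by Fisher's exact test). The polyadenylation machinery had 1 called member, Clp, with 3.73% in SC and 0.461% in SG-bgcn in the authors' deposited table. Of 4 splicing and RNA-binding regulators 3 were higher in SG-bgcn, with mub at 6.47% and 30.9%, mbl at 2.79% and 18% and Hrb27C at 0.285% and 0.503% in the authors' deposited table. Ribosomal proteins had 4 of 4 called members higher in SG-bgcn, with RpL37a at 0.00193% and 0.0306%, RpL10 at 0.00367% and 0.0328% and RpS15Aa at 0.00713% and 0.0459% in the authors' deposited table. The fourth, RpL5, had a gene level listed at 0 in SG-bgcn, so its share is not interpreted. Gnf1 had 0.0605% and 3.11%, AGO3 4.31% and 10.3%, and aly 0.588% and 8.43% in the authors' deposited table. The spermatid differentiation list had 2 called members, fzo and soti. The share of fzo was 0.129% and 100% in the authors' deposited table. The extension of soti was listed at 0 in SG-bgcn, so no direction is read from it. Of the 2 called testis proteasome paralogs, Rpn12R had 100% and 93.6%, and Prosalpha4T2 had an extension listed at 0 in SG-bgcn in the authors' deposited table, so no direction is read from it. Hub and cyst cell markers zfh1 (17%, 44.3%) and dally (0.177%, 100%) and muscle markers Tm1 (2.23%, 10.1%) and Tm2 (0.332%, 3.5%) were higher in SG-bgcn in the authors' deposited table. Gene levels were 18.18 in SC and 212.92 in SG-bgcn for Tm1, 4.52 and 66.98 for Tm2, 2.7 and 8.98 for zfh1 and 138.77 and 0.15 for dally in the authors' deposited table. Acp95EF had shares of 0.166% and 0.557% and gene levels of 349.28 and 2120.41 in the authors' deposited table.

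The 10 largest positive folds in SG-bgcn lay between 8.68 and 13.41 and include lov (0.00388% in SC, 53.2% in SG-bgcn), exu (0.00961%, 100%), ppl (0.00492%, 6.76%), Rb97D (0.12%, 61.6%) and isoQC (0.0126%, 5.56%) in the authors' deposited table, with 5 genes named by CG number. Extensions of 6 of these 10 touch an exon of another gene, as that of Rb97D does for SPARC. The 10 largest negative folds, between -8.16 and -5.59, include cwo (55.7%, 0.194%), RhoGDI (3.75%, 0.0166%) and ZnT63C (4.61%, 0.0873%) in the authors' deposited table, with 7 genes named by CG number. Act5C was among the most abundant called genes in SG-bgcn, with gene levels of 163.01 and 2054.71 and shares of 0.0401% and 0.101% in the authors' deposited table. Median extension length was 690 and 373 bases (permutation p = 2e-05, the smallest possible), and annotated 3′ UTRs were touched in 57.4% and 19.3% (Fisher's exact p = 4.00e-16). In 60 of the 145 genes higher in SC the extension was listed at 0 in SG-bgcn.

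**Figure D4:**
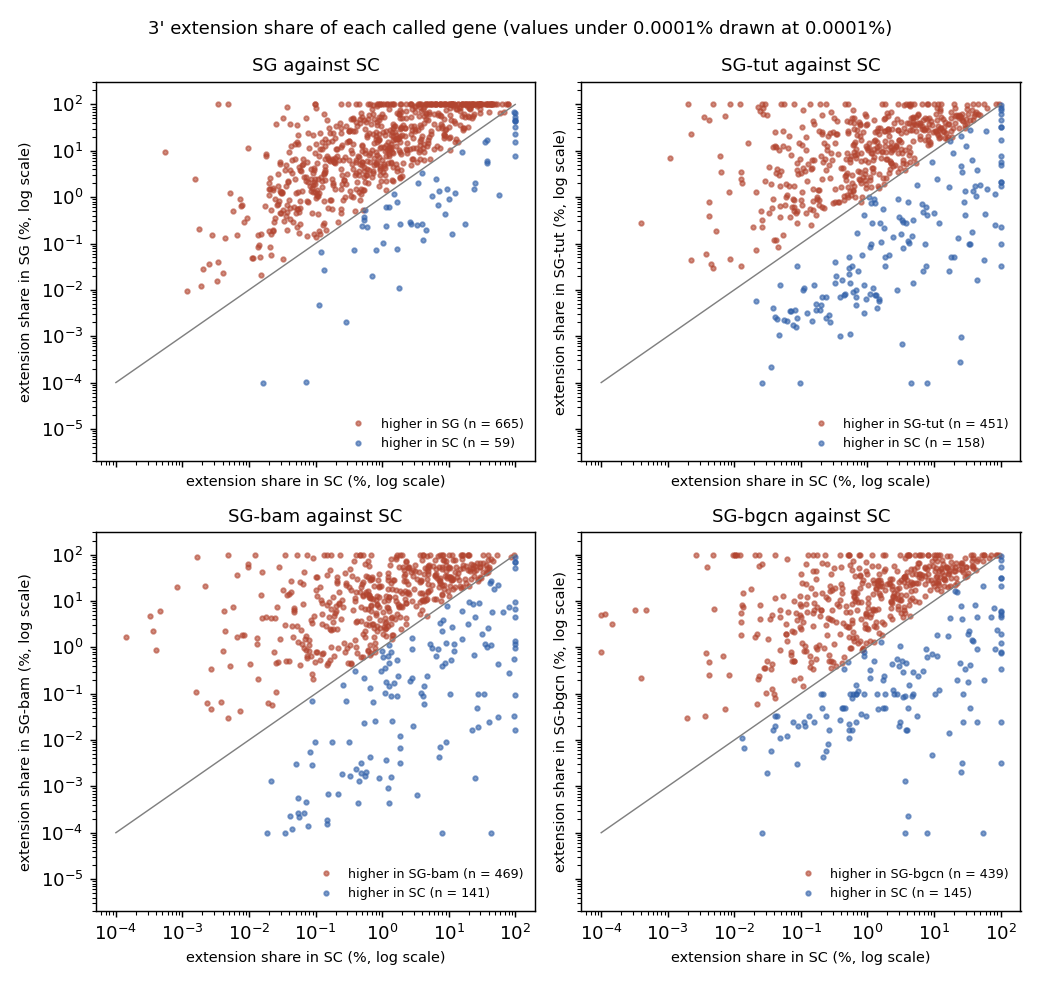
Extension share of each called gene in SC (horizontal, percent, log scale) against the mitotic group (vertical, percent, log scale), 1 panel per comparison. Red points (665, 451, 469 and 439 genes) lie above the line of equal shares and blue points (59, 158, 141 and 145 genes) below it.

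Several genes were called in dissected spermatogonia and in mutant testes alike. SG shared 222 called genes with SG-tut, of which 193 were higher in the mitotic group and 28 higher in SC in both. Independent lists would share 53.7 and 1.67. With SG-bam SG shared 219 (190 and 28, against 53.7 and 1.43), and with SG-bgcn 197 (174 and 22, against 52.2 and 1.53). The mutants shared more with each other, with 365 for SG-tut and SG-bam (290 and 75, against 37.9 and 3.99). SG-tut and SG-bgcn shared 363 (276 and 87, against 35.5 and 4.11). SG-bam and SG-bgcn shared 338 (271 and 66, against 36.8 and 3.66). All 3 mutants shared 261 genes, 211 higher in the mitotic group and 50 higher in SC, with an extension listed at 0 in a mutant for 16 of the 50. All 4 comparisons shared 108 genes higher in the mitotic group, among them stg, mub, AGO3, RpL10, RpL37a, Tm1 and Rb97D, and 16 higher in SC, among them cwo, jagn and robo1. Of these 16, CG4073 had its extension listed at 0 in the mutants, which leaves 15. Part of the excess over independent lists may come from the shared SC averages, which could not be simulated from group averages. Where SG and a mutant table held the same extension with the higher share in both, the median share was 10.7% in SG and 13.0% in SG-tut over 33 genes, 8.12% in SG and 14.2% in SG-bam over 29, and 11.8% in SG and 15.0% in SG-bgcn over 28. Gene by gene the share was higher in SG for 15 and in SG-tut for 17, in SG for 12 and in SG-bam for 15, and in SG for 14 and in SG-bgcn for 13, with no test of the difference.

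The direction of the calls differed between SG and the mutants. The 665 to 59 split of SG was compared with 451 to 158 in SG-tut (Fisher's exact p = 1.18e-18), 469 to 141 in SG-bam (p = 2.87e-14) and 439 to 145 in SG-bgcn (p = 1.23e-16). Genes are not independent, and SC is common to all 4 tables. The 222, 219 and 197 genes called in SG and in SG-tut, SG-bam and SG-bgcn count on both sides of each test. The p-values here and below treat these overlapping sets as separate. Extensions listed at 0 in the mitotic group account for 2 calls of the 59 in SG and 77, 52 and 60 of those in the mutants. Without extensions listed at 0, 57 calls were higher in SC in SG, 81 in SG-tut, 89 in SG-bam and 85 in SG-bgcn (Fisher's exact p against SG 5.06e-05, 5.11e-06 and 3.39e-06 in that order).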

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

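The test of shared bases in this part was chosen after the result was seen. For 4 genes the authors list opposite directions of the extension share in 2 of their tables, and the difference between the tables itself was not tested. Opposite directions can be read for Pi3K21B, cpo and Tbce alone, and there for different stretches of the gene, not for the same extension. In the authors' deposited table the log2 fold of the share of Pi3K21B was 2.74 in SG and -5.25 in SG-tut, that of cpo was 1.57 in SG and -4.89 in SG-bam, and that of Tbce was 3.32 in SG and -2.12 in SG-bgcn. For CG17237 the authors' deposited table gives -5.54 in SG-bam, where the extension was listed at 0 so that the value rests on the added constant, and 11.21 in SG-bgcn.

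A candidate explanation is that different stretches of the gene were measured in the 2 tables. The coordinates show that they were, as the largest number of bases shared by the 2 extensions of any of the 4 genes was 0. Whether the different stretches account for the opposite folds was not tested. For cpo the SG extension spans chromosome 3R from 18017803 to 18018022 and the SG-bam extension from 18017443 to 18017802, directly beside it. For Pi3K21B, cpo and Tbce the genotype, dissection and kit stay open as further explanations and were not tested. For CG17237 both mitotic groups are whole mutant testes made with the same kit, so there genotype and a failed estimate in SG-bam stay open, also untested.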

How the results depend on the processing

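The alternatives that use every listed gene, drop extensions touching exons of other genes, require an extension level of 1, drop extensions inside the annotated locus, or add 1 to the levels were chosen after seeing the data. Of 129 recomputed values, 108 stayed within their limits, 21 moved and 0 were classed as weaker or reversed, and the causes of the moves were not tested. The limits were wide for counts of calls. A fall from 724 to 509 in SG with an extension level of at least 1 still counted as within them. So did a fall from 609 to 408 in SG-tut with 1 added to the levels. The number of calls in SG fell from 724 to 449 with 1 added to the levels, and to 466 with at least a 4-fold difference and a level of 1. Without extensions inside the locus, the percentage of calls higher in the mitotic group was 89.4 in SG, 66.4 in SG-tut, 70.2 in SG-bam and 67.9 in SG-bgcn. Without extensions at 0 it was 84.6 in SG-tut, 83.7 in SG-bam and 83.4 in SG-bgcn, and with an extension level of at least 1 it was 78.3, 82.0 and 79.3. With 1 added it was 82.4 in SG-bam and 78.8 in SG-bgcn, and with the 4-fold rule 80.3 in SG-bam. Without extensions inside the locus, SG shared 130 calls with SG-tut, 131 with SG-bam and 114 with SG-bgcn, and the 3 mutants shared 164. With the 4-fold rule SG shared 138 with SG-tut and 141 with SG-bam. The X-linkage test in SG kept p at or below 6.07e-05 over 10 alternatives, with 1 X-linked gene higher in SC once every listed gene was used, and no list passed under any alternative run, though with the calls as reported most lists hold too few members to pass at any split. With those calls 0 lists could pass with every member on the mitotic side. No paired analysis was possible because the tables hold only group averages. For the same reason, leaving out replicates, no filter on low values, median-of-ratios scaling, a replicate block and an estimated correlation were not run. Depth per library is unknown, so no limit from depth can be given.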

Other observations

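The tests on genes of near equal level, on exons of other genes, on extensions of level 1 or more in both groups and on coverage along transcripts were chosen after the result was seen, and the genes in this and the next paragraph were picked after their values were seen. Of the 108 genes with the higher extension share in all 4 mitotic groups, 24 are X-linked and 4 lie on chromosome 4, and the SG extension of 75 touches an annotated 3′ UTR of the gene. The gene level was higher in every mitotic group for 70 of them and lower in every one for 18. Imp, an RNA-binding protein, had a gene level of 163.7 in SC and 55.32 in SG and a share of 0.83% in SC and 92.2% in SG, with 35.8% in SG-tut, 37.3% in SG-bam and 43.2% in SG-bgcn in the authors' deposited table. SRPK, a kinase of splicing factors, had 0.313% in SC and 26.9% in SG in the authors' deposited table, and 22.7%, 24.6% and 38.0% in the mutants in the same order. In the mutant comparisons the SC share was 0.941%, 0.889% and 0.941% for Imp and 0.205%, 0.287% and 0.287% for SRPK. The stretch measured can thus differ between comparisons, so these shares do not rank SG against the mutants. Jra, the fly Jun, had 0.386% in SC and 26.4% in SG, the cell polarity kinase gene par-1 had 1.67% and 19.1%, and wdb, a subunit of protein phosphatase 2A, had 6.51% and 100% in the authors' deposited table. The 4 genes on chromosome 4 are PlexA (0.476% in SC, 64.7% in SG), Ephrin (0.401%, 42.6%), Ank (0.890%, 16.7%) and gw (0.195%, 5.55%) in the authors' deposited table.

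The 16 genes listed with the higher share in SC in all 4 comparisons include 0 X-linked genes, and the SG extension of 2 touches an annotated 3′ UTR. nesd, which acts in cytokinesis of spermatocytes, had 9.52% in SC and 1.51% in SG in the authors' deposited table. Rcd5 had 0.807% in SC and 0.0733% in SG, robo1 38.2% and 5.45%, and Cib2 100% and 7.71% in the authors' deposited table. The gene levels of robo1 (2.81 in SC, 1.16 in SG) and Cib2 (0.21, 1.66) were low, so their shares rest on little signal. Among all called genes with a share of 100% in at least 1 group, 77.2% of the 123 in the SG comparison had an extension touching an annotated 3′ UTR of the gene, against 49.1% of the other SG calls. In the mutants it was 20.0% of 50 against 48.8% in SG-tut, 21.7% of 46 against 49.6% in SG-bam and 25.8% of 62 against 50.6% in SG-bgcn. An exon of another gene was touched by 9.76% of the calls at 100% in SG, against 14.1% of the others. The corresponding values were 30.0% and 15.4% in SG-tut, 30.4% and 15.2% in SG-bam and 19.4% and 16.5% in SG-bgcn.

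Among calls with a lower gene level in SG, 255 lay on the SG side and 36 on the other (87.6%, interval 83.3 to 91.2%), but this planned test of a higher level of the whole gene in SG decides nothing, because the gene level is part of the share. A different gene level as the whole cause is argued against by calls whose gene level lay within 0.5 (log2) of SC, 119 on the SG side and 16 on the other (88.1%, interval 81.5 to 93.1%), and over 4 such limits from 0.1 to 1 the lowest bound was 63.7%. Extensions touching an exon of another gene were 82 of the 665 higher in SG and 15 of the 59 higher in SC. Reads from such annotated exons cannot reach the remaining calls, of which 93.0% lay on the SG side. Dropping so few calls could not have evened the split, so that percentage is no further test. Likewise, 92.7% among the 509 of 724 calls with an extension of level 1 or more in the higher group decides nothing about noise. Noise as the whole cause is argued against by 100% of 35 calls (interval 90.0 to 100%) with that level in both groups. For calls with a lower level in SC, noise in the SC value stays open. A different coverage along transcripts in the 2 sets of dissected libraries cannot be told apart from a difference in 3′ end choice, because the folds of 5062 tests are not listed, so a shift of 3′ end choice between mitotic and meiotic germ cells remains a hypothesis.

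The lack of X-linked genes among SG calls with the higher share in SC was weighed in the same way. Annotated distal 3′ UTRs on the X as the whole cause are argued against by extensions that touch no 3′ UTR of their gene, of which 52 X-linked and 220 autosomal were higher in SG and 0 and 55 higher in SC (Fisher's exact p = 5.77e-05). A lower level of X-linked genes in SC stays open. Among calls higher in SG the median log2 fold of the gene level was 0.95 for X-linked and 0.55 for autosomal genes, a difference of 0.40 (bootstrap 95% interval -0.03 to 0.86, permutation p = 0.0688). X-linked genes made up 28.0% of 397 genes higher in SG alone and 16.6% of 465 higher in mutant testes alone (Fisher's exact p = 6.71e-05), and 18.3% of 268 found in both, so the X-linked part may belong more to dissected SG, with kit and tissue confounded.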
